A study of Homo sapiens with 37 samples.

How the data were processed

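Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on human T cells, whose source the labels give as a cell line without naming it. There were 37 samples. Of these, 36 were immunoprecipitations of 4 targets: the transcription factor Ikaros and the histone marks H3K27ac (active enhancers and promoters), H3K4me1 (enhancers) and H3K4me3 (promoters). Each target had 9 libraries, 3 in each of 3 states. Tact DMSO and Tex DMSO cells received the solvent, and Tex Mezi cells received mezigdomide, a cereblon-binding drug that directs the degradation of Ikaros and Aiolos. The series title concerns T cell exhaustion, and Tact is not expanded in the labels. Dose and duration of treatment are not given in the sources used here. The pooled input, 1 sample, came with no file and was not analysed here.

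Per the labels, the authors called narrow peaks in each library with MACS3 3.0.1 on GRCh38. Each deposited list gives, per peak, a position, a fold enrichment (a ratio over the local background), a −log10 p and a −log10 q, as the authors' peak caller wrote them, and an integer score. Numbers of sequenced reads are not given, so the depth of each library is unknown and no counting interval was computed. The number of peaks and the length they cover therefore move with depth and antibody yield as well as with occupancy. The −log10 q minimum lay between 2.0 and 2.06 in every list. The authors' fold enrichment was used only to rank peaks within a list. A base that no list covers was below the authors' calling threshold, which does not show that the protein or mark was absent.

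Samples were grouped by title. In 2 of the 36 libraries, the Tex replicate 3 Ikaros pair, the title and the library name disagreed with the treatment characteristic. They were grouped by the title, and grouping by the characteristic was an alternative. Comparisons were Tex DMSO against Tact DMSO and Tex Mezi against Tex DMSO for each target, 8 in all. Both share the 3 Tex DMSO libraries of a target, so their chance values are not independent. Nothing in the labels says that the libraries of a group came from separate cultures or donors, so the p-values measure only the spread between libraries. Replicate numbers were tested for pairing from the correlation of deviations from the group means. They paired the libraries in 3 comparisons: Ikaros in Tex against Tact DMSO, and H3K27ac and H3K4me3 in Tex Mezi against Tex DMSO. For these the model with replicate number as a block is given beside the result where it changes it.

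For each library, the bases under its peaks were summed over 19974 protein-coding loci, each being a RefSeq gene on chromosomes 1 to 22 or X with 5 kb on either side. Neighbouring loci can share bases. Loci with a mean of at least 500 bp were tested with limma 3.58.1 (trend and robust options, statmod 1.5.0, R 4.3.3) on log2 of the covered bases plus 200. Histone libraries were centred on the median of the loci covered in all 9 libraries, which were fitted together. Ikaros libraries were not scaled, since a loss of peaks across the genome would be removed by scaling, and the 6 libraries of a comparison were fitted alone. Adjusted p-values are Benjamini-Hochberg values over the loci tested, with 0.05 as the threshold. Log2 differences are from this model, with its standard error (SE), and covered lengths are means ± SD of unscaled libraries. Loci whose 3 values against 3 do not overlap were also counted, which chance gives in 10% of loci if the 6 libraries are exchangeable. Where replicate numbers pair the libraries, the share by chance can differ from 10%.

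Peaks of all 9 libraries of a target were merged into regions, and regions with a peak in 3 of 3 libraries of one group and 0 of 3 of the other were counted. When a library is left out, fewer lists have to agree on the same regions. Under this looser rule every region counted before still counts, so the total can only rise. The number of peaks per library was compared by an exact two-sided permutation test, whose smallest possible p is 0.1, with Benjamini-Hochberg adjustment over the 8 comparisons. Overlap means at least 1 bp. Ikaros occupancy of changed H3K27ac regions was compared with that of regions found in all 6 libraries by a Mantel-Haenszel odds ratio over 5 strata of region width, with a 95% interval. Regions are not independent replicates. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

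The 17 gene lists held 315 genes, 314 of them in the gene table: inhibitory receptors and exhaustion, effector cytokines and chemokines, cytotoxicity, naive and memory factors, AP-1 and NF-κB, costimulation and activation, interferon-stimulated genes, the Ikaros family with cereblon, T cell receptor signalling, regulatory T cells, glycolysis and hypoxia, cell cycle, and markers of B cells, myeloid cells, NK cells, the erythroid and megakaryocyte lineages, and non-haematopoietic cells. Some genes stand in more than 1 list. Each list was tested against the other loci with limma's camera at a preset correlation of 0.01 and again with the correlation estimated, with adjustment over the lists of a comparison. Named genes follow a rule: IKZF1 and IKZF3; per direction, the loci of smallest p with an adjusted p below 0.05, an absolute log2 difference of at least 0.5 and separate ranges, 8 for Ikaros and H3K27ac and 4 for H3K4me1 and H3K4me3; up to 4 passing members of each list, or 2 where none passed; the 5 of smallest p where fewer than 5 passed; a panel of 11 cytokine, receptor and transcription factor genes; and the 5 widest regions per direction. Not all genes the rule took are printed.

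The grouping, tests, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives were other pseudocounts (50 and 1000 bp), no filter, the other scaling, peaks with a −log10 q of at least 5, an equal number of peaks per library, the replicate block, the other set of libraries in the fit, merging of peaks within 500 bp, overlap of at least 50%, and leaving out each library. Loci of 10 kb around either gene end, gene bodies without flanks, and for the reversal leaving out each replicate number, an equal number of peaks and other chance covariances were added after seeing the data. The gene table has no strand and no genome sequence was at hand. A planned search for the Ikaros motif and loci around the transcription start were therefore not run, and a share of peaks within 1 kb of either end of a protein-coding gene took the place of a promoter share.

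The steps were tested on simulated data. Independent normal noise with the spread of the real fit was drawn around each locus mean, and 200 loci were changed, 50 at each size. A log2 change of 2 was recovered in 10% of Ikaros loci in Tex against Tact DMSO. For Ikaros in Tex Mezi against Tex DMSO it was 14%. The shares in the same 2 comparisons were 88% and 90% for H3K27ac, 66% and 64% for H3K4me1, and 98% and 96% for H3K4me3. Between 0 and 8 unchanged loci were called per comparison. The noise held no correlation between loci and no shift of a whole library, so real libraries may give lower recovery and more false calls. For Ikaros with Mezi, where most real loci passed, so few changed loci are also unlike the data.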

Results

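Peak lists of Ikaros and 3 histone marks were compared between Tact DMSO, Tex DMSO and Tex Mezi T cells, with 3 libraries per target and state. Ikaros is a zinc finger transcription factor of lymphocytes, encoded by IKZF1, and Aiolos, encoded by IKZF3, is its relative. The comparison of Tex with Tact DMSO asks which loci differ between the 2 cell states, and that of Tex Mezi with Tex DMSO asks what the drug changed in Tex cells. Numbers of reads are unknown, so how much each library gave can be judged only from its peak list.

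Ikaros peaks were far fewer after mezigdomide. Tact DMSO libraries had 75195 ± 9477 Ikaros peaks (SD, n = 3) and Tex DMSO libraries 58220 ± 2494. The 3 Tex Mezi libraries had 756, 5267 and 28052, a mean of 11358 ± 14632 and a change of −80.5% from Tex DMSO. Peaks of H3K27ac, the acetylation of active enhancers and promoters, numbered 36769 ± 1810 in Tact DMSO, 39478 ± 1483 in Tex DMSO and 44586 ± 745 in Tex Mezi, 12.9% more with the drug. The exact permutation p was 0.1, the smallest the design allows, for Ikaros in both comparisons and for H3K27ac with Mezi (BH-adjusted 0.267). With libraries paired by replicate number, an exact sign-flip test gave p = 0.25 for Ikaros in Tex against Tact DMSO and for H3K27ac with Mezi. H3K4me1 libraries had 105851 ± 5794, 102518 ± 9210 and 105855 ± 2749 peaks in Tact DMSO, Tex DMSO and Tex Mezi, and H3K4me3 libraries 27279 ± 923, 26156 ± 1721 and 26659 ± 814. For these 2 marks, and for H3K27ac in Tex against Tact DMSO, the exact p lay between 0.3 and 0.9. Peaks within 1 kb of either end of a protein-coding gene made up 22.6% of the Ikaros peaks in Tex DMSO, 28.7% for H3K27ac, 19.3% for H3K4me1 and 51.2% for H3K4me3.

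**Figure D1:**
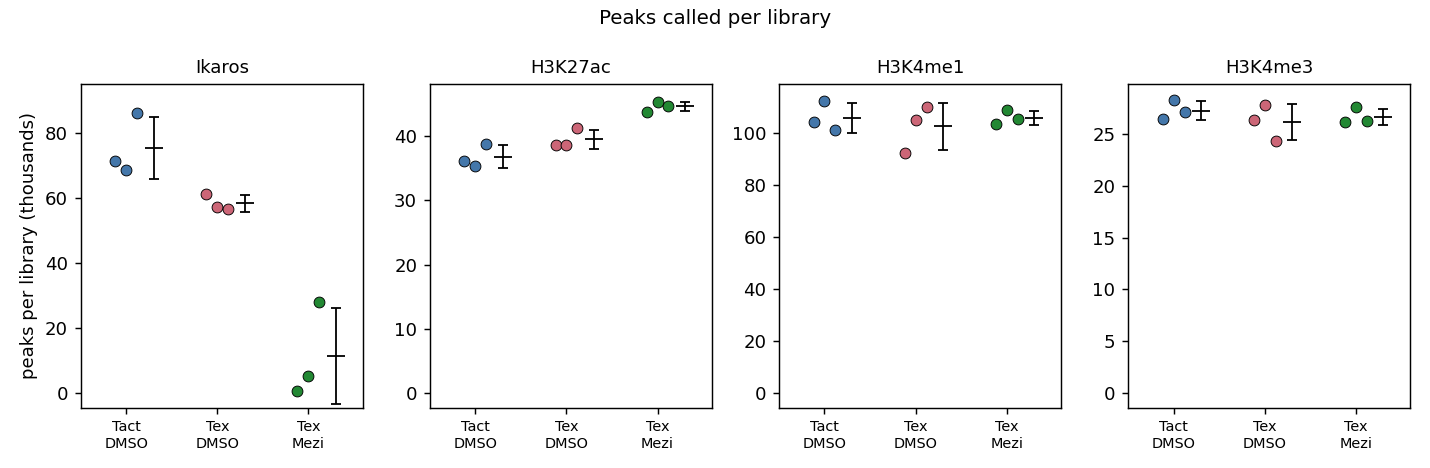
Number of peaks (y axis) per library for each target and state (x axis), with points for libraries and a black bar for the mean ± SD (n = 3). The Tex Mezi Ikaros libraries sit at 756, 5267 and 28052 peaks, all below the Tex DMSO libraries, whose mean was 58220.

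Between Tex and Tact DMSO, no Ikaros locus passed limma's test, although several had separate ranges. At ENTPD1, which encodes the ectonucleotidase CD39, Ikaros peaks covered 2.17 ± 1.5 kb in Tact and 19.1 ± 8.22 kb in Tex DMSO (SD, n = 3; adjusted p = 0.394). At TCF7, which encodes TCF-1, a factor of naive and stem-like T cells, they covered 19.7 ± 8.4 kb in Tact and 4.45 ± 2.44 kb in Tex DMSO (adjusted p = 0.604). The integrin gene ITGA9 had 1.05 ± 0.441 kb in Tact and 11.2 ± 2.47 kb in Tex DMSO (adjusted p = 0.222), and the integrin gene ITGA6 had 9.92 ± 3.09 and 1.3 ± 0.327 kb (adjusted p = 0.33). At IKZF1 itself the lengths were 29.7 ± 8.09 and 23.7 ± 4.59 kb (adjusted p = 0.995). Of 13881 loci, 0 passed and 867 had an unadjusted p below 0.05. Ranges were separate in 12.0%, against 10% by chance if the libraries were not paired. Without scaling the median difference over all loci was −0.21, and with centring −0.02, a shift of 0.20.

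As groups, Ikaros coverage in Tex against Tact DMSO lay above that of the other loci (median over all loci −0.21) in the cytotoxicity list (median log2 difference 0.21, camera adjusted p = 0.00727), the cytokines and chemokines (0.19, adjusted p = 0.0157) and the interferon-stimulated genes (0.06, adjusted p = 0.0298), and below it in the naive and memory factors (−0.40, adjusted p = 0.0408). None kept the call with an estimated correlation: adjusted p = 0.474 for the first 3 lists and adjusted p = 0.851 for the naive and memory factors. No member of any list passed over all loci. Adjusted over the list alone, 1 member was higher among the cytokines (CCL1), 1 in cytotoxicity, 1 in exhaustion (ENTPD1) and 1 among the NK cell markers; 1 was higher and 3 were lower in the regulatory T cell list, and 1 myeloid marker was lower. With replicate number as a block, which pairs the libraries here, the cytokines (0.0097) and cytotoxicity (0.00779) kept the camera call, while the interferon-stimulated genes (0.0537) and the naive and memory factors (0.085) did not. Within 10 kb of the gene ends the cell cycle list (higher, 0.0219) and the B cell markers (lower, 0.0136) passed as well, but with an estimated correlation there the adjusted p was 0.834 and 0.621.

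By region, 1966 Ikaros regions were in all 3 Tex DMSO lists and no Tact list, and 1990 in all 3 Tact lists and no Tex DMSO list. The widest of the latter lay in TCF7 (chromosome 5, 134122095 to 134126627, 4.5 kb), with another in DGKZ (chromosome 11, 46331161 to 46334308), a diacylglycerol kinase that dampens T cell receptor signals. The widest of the former lay in ZFHX3 (chromosome 16, 72875085 to 72878094, 3.0 kb). The total of 3956 was 7729 without Tact replicate 2, with 3166 only in Tex DMSO and 4563 only in Tact. It was 12055 without Tact replicate 3, with 2850 and 9205. Leaving out a library loosens the rule, so a rise is built in, and it need not be equal in both directions. These counts therefore do not show whether the near-even numbers depend on a library. The Tact replicate 3 list stood apart: its Jaccard index was 0.273 with Tact replicate 1 and 0.182 with replicate 2, against 0.513 between those 2. Ikaros peaks overlapped an H3K27ac peak in 54.8 ± 0.7% of cases in Tex DMSO and 38.0 ± 8.2% in Tact DMSO (SD, n = 3, exact permutation p = 0.1). The direction was not particular to H3K27ac. It was 74.0 ± 2.9% against 67.8 ± 7.6% for H3K4me1 (exact permutation p = 0.3) and 36.9 ± 1.4% against 29.1 ± 5.0% for H3K4me3 (0.1). The Tact Ikaros lists, with 71178, 68387 and 86019 peaks, had H3K27ac shares of 46.9%, 36.3% and 30.7%. They were longer than the Tex DMSO lists, and the part of list length was not tested.

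Ikaros coverage was lower after mezigdomide at most loci tested in Tex cells. At IKZF1 the covered length fell from 23.7 ± 4.59 to 2.34 ± 3.64 kb (SD, n = 3; log2 difference −4.60, SE 1.35, adjusted p = 0.00479), and at IKZF3 from 12.3 ± 3.21 to 0.858 ± 1.49 kb (−4.67, SE 1.16, adjusted p = 0.00166). The checkpoint receptor gene PDCD1 went from 4.35 ± 1.45 to 0.248 ± 0.43 kb (adjusted p = 0.00102) and LAG3 from 6.76 ± 2.64 to 0.327 ± 0.566 kb (adjusted p = 0.00103). ZAP70, the kinase of the T cell receptor, went from 6.85 ± 1.57 to 0.241 ± 0.418 kb (adjusted p = 0.000548), and TCF7 from 4.45 ± 2.44 to 0.104 ± 0.18 kb (adjusted p = 0.000292). KLRD1, which encodes the NK receptor CD94, went from 5.37 ± 1.2 kb to 0 in every Mezi list. At IKZF3, PDCD1, LAG3, ZAP70 and TCF7 the Mezi coverage came from 1 Mezi list, and the other Mezi lists had 0. The short Mezi lists therefore set much of the size of these differences. Of 9633 loci, 8867 passed, all lower, and 89.3% had separate ranges. The lists were not scaled, and they covered 0.27, 2.16 and 13.1 Mb with Mezi against 28.74 to 39.02 Mb in Tex DMSO. Loci therefore fall together, and these counts largely restate the difference between whole lists. The 10% expected by chance for a single locus takes no account of this. Without Tex DMSO replicate 1 the number of loci that passed was 5764. After centring of each library, which takes out a shift of 2.06 in the median, it was 2306, of which 104 were higher and 2202 lower. Centring used loci with peaks in all 6 libraries, so loci that kept Ikaros peaks in every Mezi list. Other loci tend to come out lower against that base, and the median over all loci stayed at −0.70. The 2202 therefore do not show a loss beyond a shift common to all loci. When the replicate 3 pair was grouped by its treatment characteristic, 0 loci passed limma's test, and the adjusted p of the 6 genes named with one was 0.558, the highest over their alternatives, whose lowest lay between 7.68e-07 (TCF7) and 0.000452 (IKZF1).

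Members of every gene list lost Ikaros coverage. Ikaros coverage fell at 22 of 24 measured exhaustion loci, 18 of 20 cytokines and chemokines, 13 of 16 cytotoxicity loci, 18 of 20 naive and memory factors, 22 of 22 in AP-1 and NF-κB, 19 of 20 in costimulation, 18 of 19 interferon-stimulated genes, 6 of 6 in the Ikaros family and 25 of 26 in T cell receptor signalling. In the others it fell at 7 of 8 regulatory T cell genes, 23 of 23 in glycolysis, 19 of 20 in cell cycle, 4 of 5 B cell, 4 of 4 myeloid, 4 of 4 NK, 3 of 3 erythroid and 5 of 5 non-haematopoietic markers. The counts adjusted over the list alone were the same. After centring the median over all loci was −0.70, and list medians ran from −0.27 in the erythroid and −0.42 in the non-haematopoietic markers, both above it, to −1.69 in T cell receptor signalling. Where a Mezi list holds 0 bases, the size of a fall is set by the coverage in Tex DMSO. This order can therefore follow the starting coverage and does not show a preferred loss at some lists. Fewer members passed: 14 were lower in exhaustion, 16 in T cell receptor signalling and 0 among the erythroid and the non-haematopoietic markers, and 1 cytotoxicity locus was higher. No list differed from the other loci by camera, whose lowest adjusted p was 0.313, and most lists had a camera direction up while their median was below 0.

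The Ikaros peaks found after mezigdomide mostly overlapped Tex DMSO peaks. Of the peaks in Mezi replicates 1, 2 and 3, 83.7%, 75.7% and 73.3% overlapped a peak of the same-numbered DMSO list, and 10.1%, 16.6% and 18.6% overlapped none of the 3 DMSO lists. In the DMSO lists, 80.7%, 77.5% and 87.6% of the 10% of peaks with the highest fold enrichment were overlapped by a Mezi peak, against 8.3%, 12.5% and 9.1% of the 10% with the lowest. The former shares came mainly from Mezi replicate 3, whose peaks alone overlapped 80.6%, 77.3% and 87.4%, against 26.7%, 27.3% and 31.3% for Mezi replicate 2 and 5.3%, 4.3% and 6.2% for Mezi replicate 1. There were 16564 Ikaros regions in all 3 DMSO lists and no Mezi list, 50 in the opposite case and 532 in all 6. Those lost included GATA3 (chromosome 10, 8051283 to 8059552, 8.3 kb), a T cell lineage factor, and the neighbours TMC6 and TMC8 (chromosome 17, 78123983 to 78134903, 10.9 kb). Without Tex Mezi replicate 3, the library with most peaks, the total of 16614 became 29238. The looser rule can only raise this total. With each list cut to its 756 most significant peaks it was 468, nearly even, with 225 only with Mezi and 243 only in Tex DMSO. That cut takes out any difference in peak number, so it cannot show whether peaks were lost.

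H3K27ac differed widely between Tex and Tact DMSO. At ENTPD1 (chromosome 10, 95694185 to 95877266) it covered 4.27 ± 0.602 kb in Tact and 49.3 ± 8.41 kb in Tex DMSO (SD, n = 3; log2 difference 3.45, SE 0.19, adjusted p = 4.19e-05). HAVCR2, which encodes the inhibitory receptor TIM-3, rose from 2.67 ± 1.07 to 6.66 ± 0.171 kb (1.33, SE 0.23, adjusted p = 0.00714). GNLY, which encodes the cytolytic protein granulysin, rose from 0.352 ± 0.313 to 9.98 ± 0.759 kb (4.42, SE 0.48, adjusted p = 0.000924). LEF1, a partner of TCF-1 in naive T cells, fell from 50.8 ± 21.3 to 14.3 ± 2.41 kb (−1.73, SE 0.30, adjusted p = 0.0072), and FOXP1, a factor of T cell quiescence, from 106 ± 30.1 to 11.2 ± 7.92 kb (−3.44, SE 0.56, adjusted p = 0.00537). HLX, a homeobox factor, was listed at 0 in Tact and had 3.85 ± 0.443 kb in Tex DMSO, while the glycosyltransferase gene MGAT5 had 7.1 ± 2.11 kb in Tact and was listed at 0 in Tex DMSO. Within 10 kb of the gene ends the call ended for ENTPD1 (adjusted p over 16 alternatives 2.61e-05 to 0.388) and FOXP1 (0.00378 to 0.137). For IFNG, the interferon gamma gene, lengths of 0.433 ± 0.377 and 2.43 ± 1.25 kb passed (adjusted p = 0.0407). Its call ended under 8 of 16 alternatives (0.00415 to 0.118), among them those without Tex DMSO replicate 1 (0.104) or 3 (0.118) and without Tact replicate 2 (0.0674) or 3 (0.0592).

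The interferon-stimulated genes had the lowest camera p among the lists for H3K27ac. Of 24 measured, 8 rose, 0 fell and 16 did not pass (11 higher adjusted over the list alone), with a camera adjusted p of 0.00105 and adjusted p = 0.537 with an estimated correlation. XAF1, an apoptosis-promoting interferon target, rose from 1.48 ± 0.196 to 4.61 ± 0.12 kb (SD, n = 3; adjusted p = 0.000138) and OAS1, an antiviral RNA sensor, from 1.14 ± 0.296 to 3.35 ± 0.56 kb (adjusted p = 0.00313). In cytotoxicity 4 of 17 rose, none fell (5 higher adjusted over the list alone), and the camera adjusted p was 0.045, with adjusted p = 0.648 with an estimated correlation. Beside GNLY, the granzyme gene GZMH rose from 0.688 ± 0.0332 to 2.42 ± 0.561 kb (adjusted p = 0.00103). Among 19 naive and memory factors 1 rose and 5 fell (1 and 7 adjusted over the list alone). The camera adjusted p was 0.0197, with adjusted p = 0.485 with an estimated correlation, and 0.0734 within 10 kb of the gene ends. ID3, an inhibitor of E-protein transcription factors, had 2.14 ± 0.0803 kb in Tact and was listed at 0 in Tex DMSO (adjusted p = 0.000249). TCF7, with 21.2 ± 1.27 and 5.21 ± 3.89 kb, did not pass (adjusted p = 0.0774).

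The exhaustion list went both ways, with 6 of 26 higher and 5 lower (7 and 5 adjusted over the list alone, camera adjusted p = 0.513). CD38, an NAD-consuming surface enzyme, rose from 1.64 ± 0.286 to 5.73 ± 0.696 kb (SD, n = 3; adjusted p = 0.00183), whereas IRF4, a factor induced by T cell receptor signals, fell from 15.1 ± 1.6 to 9.51 ± 0.533 kb (adjusted p = 0.0054). PDCD1 had 5.36 ± 2.36 and 6.09 ± 1.89 kb (adjusted p = 0.716), LAG3 6.86 ± 1.35 and 9.54 ± 0.74 kb (0.0821), and TOX 4.9 ± 2.98 and 8.35 ± 3.36 kb (0.268). Of 23 cytokines and chemokines 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.112, and 0.00269 within 10 kb of the gene ends, where it was 0.243 with an estimated correlation), including the chemokine gene CXCL10, listed at 0 in Tact and at 3.67 ± 1.55 kb in Tex DMSO. In T cell receptor signalling 1 rose and 5 fell of 26, as also adjusted over the list alone, with MALT1, a scaffold of NF-κB activation, falling from 4.45 ± 1.22 to 1.36 ± 0.0928 kb (adjusted p = 0.000775). In the regulatory T cell list 2 rose and 3 fell of 10 (3 and 3 adjusted over the list alone): CCR8, a chemokine receptor, was listed at 0 in Tact and had 2.79 ± 0.565 kb in Tex DMSO, and the decoy receptor gene IL1R2 fell from 8.19 ± 0.295 to 2.61 ± 0.0809 kb.

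For the remaining lists the H3K27ac counts higher and lower were 4 and 3 of 26 in cell cycle, 2 and 3 of 22 in AP-1 and NF-κB, 2 and 0 of 20 in costimulation, 1 and 1 of 23 in glycolysis and 0 and 1 of 8 in the Ikaros family. Adjusted over the list alone, cell cycle had 5 and 3, the Ikaros family 1 and 1, and the other 3 lists the same counts. Markers of other cell types had 0 and 0 of 6 (B cell), 1 and 0 of 3 (myeloid), 1 and 0 of 6 (NK), 0 and 0 of 3 (erythroid) and 1 and 0 of 4 (non-haematopoietic), with a camera adjusted p of 0.353 or more for all of these lists, though cell cycle passed within 10 kb of the gene ends (higher, 0.0241; adjusted p = 0.243 there with an estimated correlation). Adjusted over the list alone these were 0 and 2, 2 and 0, 1 and 1, 0 and 0, and 1 and 0. Median and mean differed in sign for costimulation (−0.08 and 0.17), the NK markers (−0.02 and 0.33) and the erythroid markers (−0.08 and 0.18). In all, 2074 of 12075 loci passed, 1142 higher and 932 lower, and 34.8% had separate ranges (10% by chance). The number was 1371 without Tex DMSO replicate 2, 1244 without Tex DMSO replicate 3, 1208 without Tact replicate 3, and 1312 with only the 6 libraries compared in the fit.

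By region, 3008 H3K27ac regions were found only in Tex DMSO and 1636 only in Tact DMSO. The widest of the former lay in ENTPD1 (chromosome 10, 95788629 to 95799333, 10.7 kb) and NRP2 (chromosome 2, 205681500 to 205689977, 8.5 kb), which encodes a semaphorin co-receptor. The widest of the latter lay in LEF1 (chromosome 4, 108091696 to 108096654, 5.0 kb) and FYN (chromosome 6, 111863447 to 111868306, 4.9 kb), a kinase of T cell receptor signalling. An Ikaros peak of all 3 Tex DMSO libraries overlapped 63.2% of the regions found only in Tex DMSO, 14.9% of those found only in Tact and 75.9% of those in all 6 libraries. At equal region width the odds ratio against regions in all 6 was 1.0 (95% interval 0.91 to 1.1) for regions only in Tex DMSO and 0.12 (0.1 to 0.14) for regions only in Tact. Against regions in 1 to 5 of the 6 libraries, it was 2.84 (2.62 to 3.09) for regions only in Tex DMSO and 0.34 (0.3 to 0.39) for regions only in Tact. Since Ikaros peaks often lie in acetylated chromatin, and regions found in only 1 state lack H3K27ac in the other by definition, these ratios carry that difference too.

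**Figure D2:**
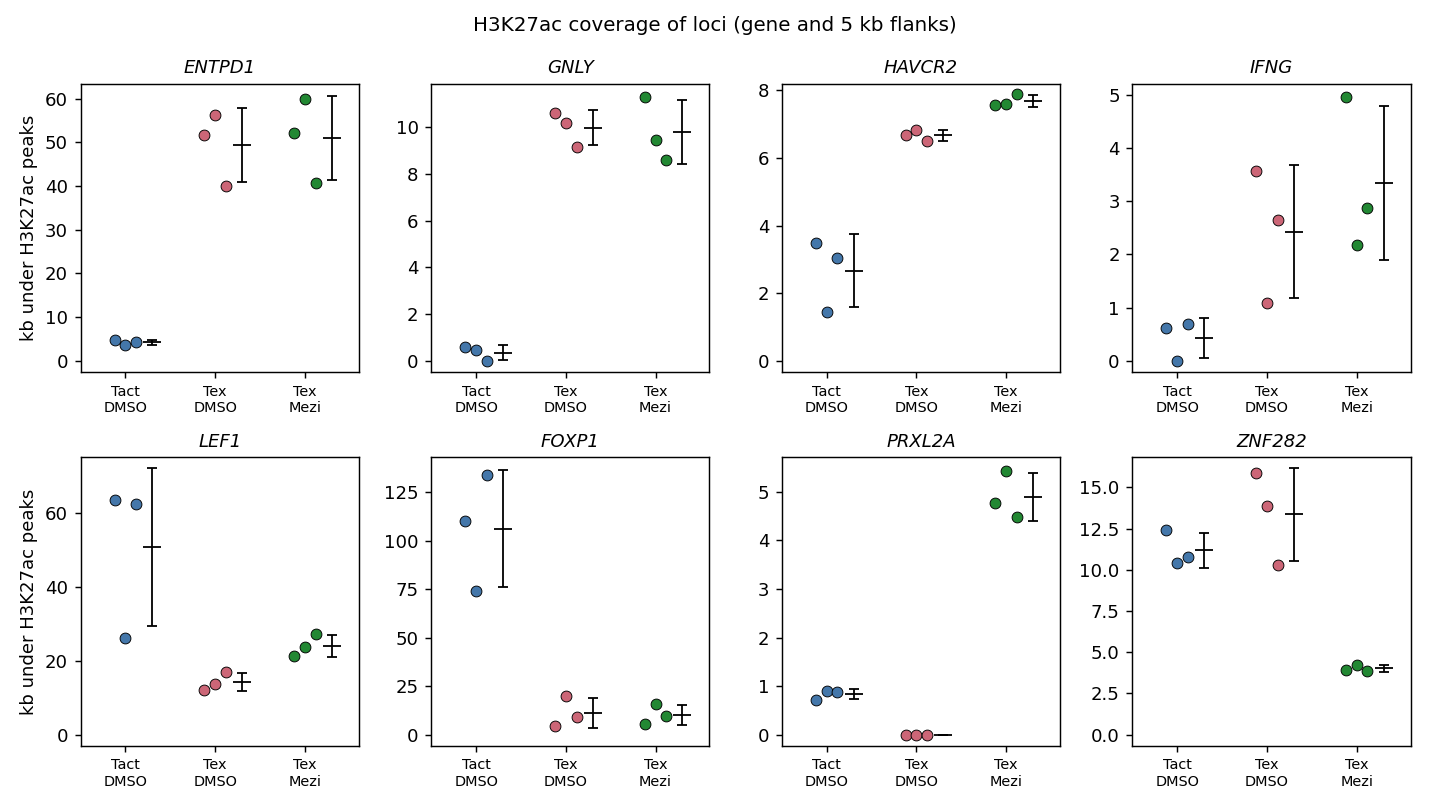
Length under H3K27ac peaks (kb, y axis) at 8 loci in the Tact DMSO, Tex DMSO and Tex Mezi libraries (x axis), with points for libraries and a black bar for the mean ± SD (n = 3). ENTPD1, with means of 4.27, 49.3 and 51 kb, and LEF1, with 50.8, 14.3 and 24.1 kb, differed between Tact and Tex DMSO, ZNF282, with 11.2, 13.3 and 4.02 kb, differed between Tex DMSO and Tex Mezi, and PRXL2A, with 0.833, 0 and 4.9 kb, differed in both comparisons.

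After mezigdomide, H3K27ac in Tex cells was higher at more loci than it was lower. PRXL2A, which encodes a redox-regulatory protein, was listed at 0 in Tex DMSO and had 4.9 ± 0.487 kb in Tex Mezi (SD, n = 3; adjusted p = 9.44e-06). The histone acetyltransferase gene KAT7 rose from 1.62 ± 0.159 to 6.17 ± 0.463 kb (log2 difference 1.73, SE 0.10, adjusted p = 0.000394) and the channel gene PANX1 from 2.14 ± 0.146 to 6.83 ± 0.0812 kb (1.51, SE 0.09, adjusted p = 0.000394). TNFRSF10A, a death receptor for TRAIL, was listed at 0 in Tex DMSO and had 1.74 ± 0.178 kb with Mezi, beside 1.52 ± 0.386 kb in Tact DMSO. The zinc finger gene ZNF282 fell from 13.3 ± 2.86 to 4.02 ± 0.195 kb (−1.73, SE 0.16, adjusted p = 0.00156). The transcription factor gene HLF fell from 1.58 ± 0.147 kb to 0 in every Mezi list (adjusted p = 0.000394), as did CD22, a lectin of B cells, from 1.42 ± 0.788 kb (adjusted p = 0.0022). Of 12075 loci, 578 passed, 445 higher and 133 lower, and 32.0% had separate ranges (10% by chance if the libraries were not paired). With replicate number as a block, which pairs the libraries here, 612 passed, 449 higher and 163 lower. Of these, 461 were among the 578 of the main fit, to which the counts below refer. The number was 308, 227 and 168 without Mezi replicates 1, 2 and 3, and 232 and 360 without Tex DMSO replicates 2 and 3.

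At the exhaustion loci no H3K27ac difference with Mezi passed by limma, 0 of 26 against 578 of all 12075 loci. At an unadjusted p below 0.05 the counts were 1 of 26 and 2237 of 12075. Lengths in Tex DMSO and Tex Mezi were 6.09 ± 1.89 and 4.93 ± 1.1 kb at PDCD1 (SD, n = 3; adjusted p = 0.677), 6.66 ± 0.171 and 7.68 ± 0.17 kb at HAVCR2 (0.828), 49.3 ± 8.41 and 51 ± 9.61 kb at ENTPD1 (0.96) and 8.35 ± 3.36 and 6.47 ± 3.19 kb at TOX (0.679). The adjusted p was 0.452 at LAG3, 0.334 at TIGIT, 0.584 at CTLA4 and 0.319 at TCF7. IFNG had 2.43 ± 1.25 and 3.34 ± 1.45 kb (0.78), TNF 8.5 ± 2.34 and 10.3 ± 1.13 kb (0.56) and IL2 1.46 ± 0.734 and 1.98 ± 1.07 kb (0.868). At the genes of the drug's targets, IKZF1 had 56.2 ± 6.89 and 50.9 ± 8.39 kb (0.53) and IKZF3 17.6 ± 6.72 and 14.6 ± 3.85 kb (0.686). GZMH rose from 2.42 ± 0.561 to 5.39 ± 0.773 kb (adjusted p = 0.0154), a call that ended without flanks (0.456) and without Mezi replicate 1 (0.0507) or 3 (0.0693), in a range of 0.0101 to 0.456 over 16 alternatives. EGR2, an early growth response factor, fell from 6.92 ± 1.27 to 3.75 ± 0.177 kb (adjusted p = 0.0117), which ended without Mezi replicate 3 (0.0594; range 0.00846 to 0.0594).

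No list passed the camera test in H3K27ac with Mezi. The lowest adjusted p, 0.0594, was that of the regulatory T cell genes, with a lower direction, and it was 0.0245 within 10 kb of the gene ends; with an estimated correlation it was 0.8, and 0.691 within 10 kb of the gene ends. Of the 10 measured there, 0 rose and 1 fell (0 and 2 adjusted over the list alone). The other counts higher and lower were 1 and 0 of 23 cytokines, 1 and 0 of 17 in cytotoxicity, 1 and 0 of 19 naive and memory factors, 0 and 1 of 20 in costimulation, 0 and 2 of 26 in cell cycle, 0 and 1 of 6 B cell markers and 1 and 0 of 4 non-haematopoietic markers. No locus passed among 24 interferon-stimulated genes, 22 in AP-1 and NF-κB, 26 in T cell receptor signalling, 23 in glycolysis, 8 in the Ikaros family, 3 myeloid, 6 NK and 3 erythroid markers. Adjusted over the list alone, B cell markers had 1 and 1, and the remaining lists the counts given. At a log2 change of 1, 62% of simulated H3K27ac changes were recovered in this comparison.

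By region, 3206 H3K27ac regions were found only with Mezi and 881 only in Tex DMSO. The widest of the former lay in DCPS (chromosome 11, 126336181 to 126342888, 6.7 kb), a decapping enzyme gene, and the widest lost region within a gene lay in WWOX, with another in ZNF282 (chromosome 7, 149205273 to 149208814, 3.5 kb). An Ikaros peak of all 3 Tex DMSO libraries overlapped 30.5% of the gained and 36.9% of the lost regions, against 76.3% of the 20443 regions in all 6 libraries. At equal region width the odds ratio was 0.26 (95% interval 0.24 to 0.28) for gained and 0.38 (0.32 to 0.43) for lost regions. Against regions in 1 to 5 of the 6 libraries, it was 0.99 (0.91 to 1.07) for gained regions and 1.35 (1.17 to 1.55) for lost ones. Gained regions had no H3K27ac peak in Tex DMSO by definition, so a lower share than in all 6 was built in.

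For H3K4me1, the mark of enhancers, fewer loci passed between Tex and Tact DMSO than for H3K27ac. A simulated log2 change of 1 was recovered in 4% of H3K4me1 loci and 68% of H3K27ac loci here, so the counts do not rank the marks. ITGA9 rose from 1.7 ± 0.57 kb in Tact to 32.8 ± 3.5 kb in Tex DMSO (SD, n = 3; log2 difference 4.13, SE 0.19, adjusted p = 2.39e-05), and ITGA6 fell from 23.3 ± 3.8 to 4.16 ± 1.0 kb (−2.47, SE 0.22, adjusted p = 0.000733). The chemokine gene CCL1 was listed at 0 in Tact and had 5.83 ± 1.34 kb in Tex DMSO, and GNLY rose from 0.557 ± 0.335 to 9.85 ± 0.834 kb (3.80, SE 0.29, adjusted p = 0.000375). CDH3, a cadherin gene, fell from 9.73 ± 1.52 to 2.79 ± 0.584 kb (adjusted p = 0.00178). Of 14647 loci, 629 passed, 406 higher and 223 lower, and 19.5% had separate ranges (10% by chance). The number was 93 with only the 6 libraries compared in the fit, 215 and 206 without Tex DMSO replicates 2 and 3, and 245, 319 and 1018 without Tact replicates 1, 2 and 3. The lists of Tact replicate 3 and Tex DMSO replicate 1 were closer to each other (Jaccard index 0.518) than to their own groups. The index was 0.451 and 0.425 with Tact replicates 1 and 2 for the former. For the latter it was 0.459 and 0.452 with Tex DMSO replicates 2 and 3.

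By camera, H3K4me1 was higher in Tex DMSO at the interferon-stimulated genes (3 of 23 higher, 0 lower; adjusted p = 0.00721), the cytokines (3 higher, 1 lower of 26; 0.00755) and cytotoxicity (2 of 18 higher, 0 lower; 0.00755), and lower at the naive and memory factors (3 of 20 lower, 0 higher; 0.0231). The calls were lost with an estimated correlation: adjusted p = 0.426 for the first 3 lists and adjusted p = 0.55 for the last, whose adjusted p within 10 kb of the gene ends was 0.157. There the cell cycle list passed (higher, 0.0244, against 0.256 with the main loci), but the adjusted p there was 0.201 with an estimated correlation. Adjusted over the list alone, these lists had 6, 4 and 3 higher and, for the naive and memory factors, 4 lower. Of 27 exhaustion loci, 0 passed by limma and 6 had an unadjusted p below 0.05. By region, 3240 H3K4me1 regions were found only in Tex DMSO and 4224 only in Tact DMSO, in total 7464. Leaving out a library loosens the rule, which raises the total by itself. Without Tex DMSO replicate 1 the total was 13754 and the majority turned, with 7806 only in Tex DMSO and 5948 only in Tact. Without Tact replicate 3 it was 14297, with 4543 and 9754.

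With Mezi, H3K4me1 passed at 84 of 14647 loci, 72 higher and 12 lower, and 22.6% had separate ranges (10% by chance). ACSL6, an acyl-CoA synthetase gene, rose from 10.5 ± 2.22 to 26.0 ± 1.33 kb (SD, n = 3; log2 difference 1.51, SE 0.15, adjusted p = 0.0204). No H3K4me1 call of this comparison held throughout. With replicate number as a block, 0 loci passed in limma. Without Mezi replicate 1, 2 or 3 or Tex DMSO replicate 2, 0 loci passed in limma, against 34 without Tex DMSO replicate 1 and 6 without replicate 3, and with all libraries 1807 had an unadjusted p below 0.05. For ACSL6 the adjusted p was 0.0747, 0.176 and 0.174 without Mezi replicates 1, 2 and 3 and 0.0758 without Tex DMSO replicate 2, in a range of 0.00405 to 0.176. No list passed by camera (lowest adjusted p 0.116, T cell receptor signalling and regulatory T cells, both 0.0349 within 10 kb of the gene ends and 0.816 there with an estimated correlation). Without scaling the median difference over all loci moved by −0.20, and 21 loci passed. There were 4037 regions only with Mezi and 1717 only in Tex DMSO, in total 5754. Under the looser rule the total was 9432 without Mezi replicate 1 (6362 and 3070) and 9153 without Tex DMSO replicate 3 (5797 and 3356). It was 9558 without Tex DMSO replicate 1, where the regions were about even, with 4875 only with Mezi and 4683 only in Tex DMSO.

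H3K4me3, the mark of promoters, differed between Tex and Tact DMSO at TCF7 and at interferon-stimulated genes. TCF7 fell from 13.5 ± 2.99 to 1.86 ± 0.937 kb (SD, n = 3; log2 difference −2.75, SE 0.37, adjusted p = 0.00606), and FOXP3, the regulatory T cell factor, from 3.36 ± 0.41 to 1.42 ± 0.206 kb (−1.07, SE 0.13, adjusted p = 0.00349). The flippase gene ATP8B4 rose from 2.65 ± 0.372 to 16.3 ± 1.26 kb (2.61, SE 0.12, adjusted p = 2.89e-05), and FCMR, which encodes the Fc receptor for IgM, fell from 7.98 ± 0.917 to 0.979 ± 0.259 kb (−2.74, SE 0.19, adjusted p = 0.000275). CD86, a costimulatory ligand, was listed at 0 in Tact and had 5.48 ± 1.07 kb in Tex DMSO. Of 24 interferon-stimulated genes 8 rose and 0 fell (14 higher adjusted over the list alone), with a camera adjusted p of 3.54e-09 and adjusted p = 0.563 with an estimated correlation. Among them were RIGI, the cytosolic RNA sensor, from 1.74 ± 0.171 to 3.43 ± 0.462 kb (adjusted p = 0.00368), and CMPK2, a mitochondrial nucleotide kinase gene, from 2.11 ± 0.248 to 4.01 ± 0.616 kb (adjusted p = 0.00734). In exhaustion 3 of 24 were higher and 1 lower (3 and 2 adjusted over the list alone), and no list but the interferon-stimulated genes passed by camera.

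Of 14179 loci, H3K4me3 passed at 742 between Tex and Tact DMSO, 310 higher and 432 lower, and 26.8% had separate ranges (10% by chance). Without scaling 946 passed, 235 higher and 711 lower, so that the share higher was 24.8% in place of 41.8%. The number was 250 with only the 6 libraries compared in the fit, 345, 294 and 239 without Tex DMSO replicates 1, 2 and 3, and 1499 without Tact replicate 2, where the majority turned, with 773 higher and 726 lower. There were 587 regions only in Tex DMSO and 748 only in Tact DMSO, in total 1335. Under the looser rule the total was 2074 without Tact replicate 1 and 2268 without Tact replicate 2.

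With Mezi, H3K4me3 rose at few loci. SLC15A3, which encodes a lysosomal peptide transporter, was listed at 0 in Tex DMSO and had 3.16 ± 0.223 kb with Mezi (SD, n = 3; adjusted p = 0.000276), beside 1.27 ± 0.291 kb in Tact DMSO. SH3RF2, a scaffold protein gene, rose from 0.545 ± 0.0854 to 4.02 ± 0.155 kb (log2 difference 2.45, SE 0.14, adjusted p = 0.000279) and PLPP6, a lipid phosphatase gene, from 2.16 ± 0.252 to 4.97 ± 0.17 kb (1.09, SE 0.08, adjusted p = 0.00169). Of 14179 loci 30 passed, 29 higher and 1 lower, and 18.9% had separate ranges (10% by chance if the libraries were not paired). With replicate number as a block, which pairs the libraries here, 18 passed. The number was 15, 7 and 10 without Mezi replicates 1, 2 and 3 and 13, 12 and 15 without Tex DMSO replicates 1, 2 and 3, and 139 with only the 6 libraries compared in the fit.

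By camera, H3K4me3 was lower with Mezi in cytotoxicity (16 measured, adjusted p = 0.00654) and costimulation (20 measured, adjusted p = 0.00844), with adjusted p = 0.242 for both with an estimated correlation, and no member of either passed, also adjusted over the list alone. With the replicate block, the regulatory T cell genes (lower, 0.0429) and the interferon-stimulated genes (higher, 0.0361) passed as well, with adjusted p = 0.242 and adjusted p = 0.63 with an estimated correlation. The cytokines had a median of −0.14, a mean of 0.10 and a lower camera direction (adjusted p = 0.408). There were 490 regions only with Mezi and 179 only in Tex DMSO, in total 669. Under the looser rule the total was 1175 without Mezi replicate 1 (876 and 299) and 1016 without Tex DMSO replicate 2 (732 and 284). It was 1086 without Tex DMSO replicate 3, where the regions were about even, with 565 only with Mezi and 521 only in Tex DMSO.

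Whether Mezi turned back the difference between Tex and Tact was tested across loci. Since both comparisons share the Tex DMSO libraries, unchanged groups of independent libraries would give a correlation of −0.5. The correlation across loci, which are not independent replicates, was 0.05 for H3K27ac, 0.08 for H3K4me1, −0.04 for H3K4me3 and −0.37 for Ikaros. The covariance lay above that of simulated independent libraries by 0.06, 0.136, 0.017 and 0.07 for H3K27ac, H3K4me1, H3K4me3 and Ikaros. With a chance covariance that keeps libraries of the same replicate number together, the differences were 0.046, 0.2, −0.001 and −0.262, and with one from the spread of the Tex DMSO libraries alone 0.069, 0.168, 0.012 and −0.116, so the sign turned for Ikaros under both and for H3K4me3 under the former. The difference from the simulated one ranged from 0.022 to 0.081, from −0.026 to 0.221, from 0.009 to 0.033 and from 0.04 to 0.32 when each replicate number was left out, with the sign turned for H3K4me1 without replicate 3. For Ikaros these values cannot decide the question. Its unscaled Mezi lists covered 0.27, 2.16 and 13.1 Mb, against a mean of 34.4 Mb in Tex DMSO. With so little left, the difference with Mezi largely follows the Tex DMSO level, which also enters the difference from Tact. A negative covariance can come from this alone.

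H3K27ac passed in both comparisons at 147 loci, 68 of them with opposite signs. The interleukin-6 receptor gene IL6R, with 8.05 ± 1.82, 1.18 ± 0.219 and 5.01 ± 0.478 kb in Tact DMSO, Tex DMSO and Tex Mezi (SD, n = 3), was 1 of 49 loci lower in Tex and higher with Mezi, where 34.3 would be expected if the calls of the 2 comparisons were independent, which their shared libraries do not make them. Others were TNFRSF10A and PRXL2A. CCR8, with 0, 2.79 ± 0.565 and 1.27 ± 0.368 kb in the same states, was 1 of 19 loci higher in Tex and lower with Mezi (12.6 expected). Its call with Mezi (adjusted p = 0.0412) ended without Mezi replicates 1 (0.0993), 2 (0.0951) and 3 (0.0876) and without Tex DMSO replicates 2 (0.158) and 3 (0.128), in a range of 0.0228 to 0.158 over 15 alternatives. Another 64 were higher in both (42.1 expected), among them GZMH and INHBA, which encodes a subunit of activin A and had 0, 0.579 ± 0.167 and 5.52 ± 1.04 kb, and 15 were lower in both (10.3 expected). IL6R and INHBA, and TNFRSF10A as a locus of both comparisons, were chosen after their values were seen. H3K4me1 passed in both comparisons at 15 loci, 6 with opposite signs, and H3K4me3 at 8, 6 with opposite signs, which included IL6R and SLC15A3.

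**Figure D3:**
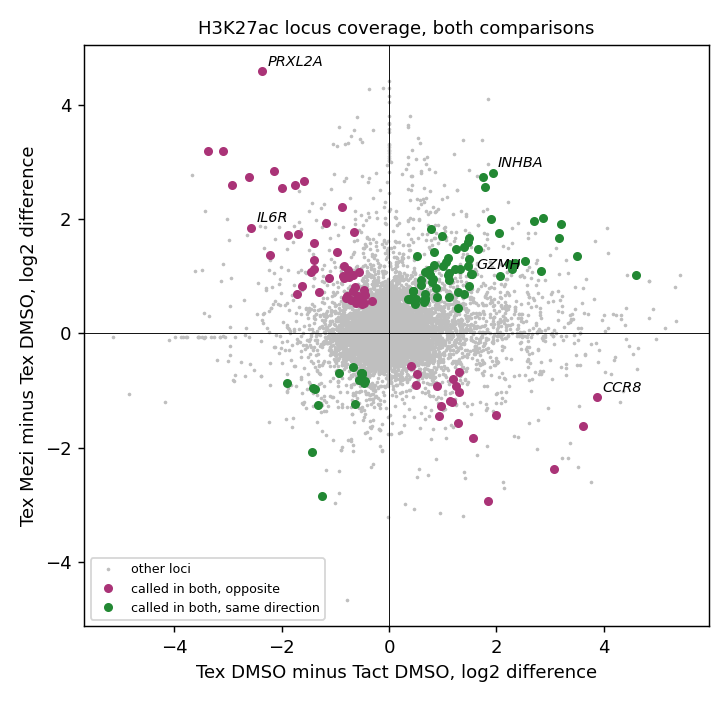
Log2 difference in H3K27ac coverage in Tex DMSO against Tact DMSO (x axis) and in Tex Mezi against Tex DMSO (y axis), with a point per locus. The correlation across loci was 0.05, and of the 147 loci that passed in both comparisons 68 had opposite signs, such as IL6R, PRXL2A and CCR8.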

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

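The tests on the unequal Ikaros lists, the H3K27ac imbalance and the Ikaros regions found only with Mezi were chosen after those results were seen, and so were the bounds set for the other splits of the libraries, whose counts were planned.

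Peaks on unplaced scaffolds, which the comparisons did not use, numbered above 3 in every library of 4 groups: 130 in the Tact DMSO Ikaros lists, 118 in the Tex DMSO Ikaros lists, 23 in the Tex Mezi Ikaros lists and 15 in the Tex Mezi H3K4me1 lists. They made up 0.058%, 0.068%, 0.067% and 0.005% of the peaks of those groups. The pooled share of the Tex Mezi Ikaros lists hides unequal libraries. Replicates 1, 2 and 3 had 15, 4 and 4 scaffold peaks beside 756, 5267 and 28052 peaks on the chromosomes analysed. These lists also had 7, 9 and 6 mitochondrial peaks, against 0 or 1 in each DMSO Ikaros list. The cause was not tested.

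The 3 Tex Mezi Ikaros libraries had 756, 5267 and 28052 peaks. An exchange of the replicate 3 labels is argued against by the Tex DMSO replicate 3 list, whose mean Jaccard index with the other Tex DMSO lists was 0.513, against 0.493 for the other pair. A weaker action of the drug in replicate 3 that carries into the histone marks in proportion is argued against by the slope of the Mezi difference in pair 3, which was between 0.93 and 1.13 of the mean of the other pairs over the 3 marks. A lower yield or depth of the shorter lists remains open and had the values it needs: 97.1% of the replicate 1 peaks and 95.8% of the replicate 2 peaks lay in the replicate 3 list, and they overlapped its strong peaks, with a median fold percentile of 96.9 and 88.4 against 48.7 and 42.2 for the rest. A graded loss of Ikaros between the libraries would leave strong peaks in the same way and may equally account for the pattern, and neither the depth nor the Ikaros protein level was at hand to separate them.

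With Mezi, H3K27ac was higher at 445 and lower at 133 of the loci that passed. A larger number of peaks in the Mezi libraries is argued against as the whole cause, since 71.6% were higher with equally many peaks per library, and so are weak peaks near the calling threshold, since 74.3% were higher at a −log10 q of at least 5. Unequal depth or antibody yield that acts other than through the number of peaks could not be tested. As a hypothesis, loss of Ikaros, which can recruit deacetylase complexes, may raise acetylation. The Ikaros share of the gained regions does not decide it, since they were chosen for having no H3K27ac peak in Tex DMSO, where 54.8% of the Ikaros peaks overlapped one. Of the 16564 Ikaros regions found only with DMSO, 1.0% overlapped a gained and 1.7% a lost H3K27ac region, although gained regions numbered 3206 and lost ones 881; this order does not favour the hypothesis, but the same choice of regions bears on it.

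Ikaros antibody regions found in all 3 Mezi lists and no Tex DMSO list numbered 50, where a degrader of Ikaros would leave few. Of these, 34, or 68.0%, overlapped an H3K27ac region gained with Mezi, against 15.6% of the 532 Ikaros regions in all 6 lists and 1.0% of those found only with DMSO. Part of this contrast was built in, since gained regions had no H3K27ac peak in Tex DMSO by definition. H3K27ac regions of all 6 libraries overlapped 64.1% of the 532 and 50.3% of those only with DMSO, but 0.0% of the 50. Of the 50, 58.0% also overlapped a gained H3K4me1 region. An antibody signal that follows newly acetylated chromatin, a technical background of open regions, could give the overlap but is not shown by it. Remaining Ikaros that binds newly active regions would give the same overlap and stays open, since no library without Ikaros was analysed here. The 2 widest lay 126605 and 103240 bp from INHBA.

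Each comparison of 3 with 3 libraries allows 10 splits, too few for a share below 0.05. For the loci that passed, the real split alone gave a count as large (1 of 10) in all comparisons but Ikaros in Tex against Tact DMSO, where all 10 splits gave 0. The real counts, with the highest of the other splits, were 8867 and 0 for Ikaros with Mezi, 2074 and 0 for H3K27ac, 629 and 1 for H3K4me1 and 742 and 0 for H3K4me3 in Tex against Tact DMSO, and 578 and 1, 84 and 0, and 30 and 0 for the same marks with Mezi. For the regions in 3 lists against 0, the real split alone was as large (1 of 10) in all 8 comparisons. In Tex against Tact DMSO these were 3956 and 3616 for Ikaros, 4644 and 402 for H3K27ac, 7464 and 3090 for H3K4me1, and 1335 and 178 for H3K4me3. With Mezi they were 16614 and 851, 4087 and 605, 5754 and 1857, and 669 and 208. The 3616 came from the split that puts Tact replicate 3 with Tex DMSO replicates 1 and 3, which keeps 2 of the pairs together. Where the numbers pair the libraries, the other splits that also part all 3 pairs gave at most 559 (Ikaros in Tex against Tact DMSO), 68 (H3K27ac with Mezi) and 64 (H3K4me3 with Mezi).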

How the results depend on the processing

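Loci of 10 kb around either gene end, gene bodies without flanks, and for the reversal leaving out replicate numbers, an equal number of peaks and other chance covariances were chosen after the data were seen; the other alternatives were planned. The planned loci around the transcription start and the Ikaros motif were not run, and the planned share of opposite signs is not given because its simulated groups held no difference. A named locus that passed was counted once per target and comparison, which gave 250 calls. Of their 3904 values under the alternatives, 3349 kept direction and call, 551 kept direction only and 4 turned. The numbers of loci stayed within 1.5 times in 80 of 129 alternatives, the regions in 66 of 80 and the number of lists that passed in 15 of 24. The difference in peak number kept its sign in 62 of 66. Agreements of 0 with 0 are among these and carry no information. They make up all alternatives for Ikaros loci in Tex against Tact DMSO, and some of those for lists. Depth is unknown, so how far it limits each list was not tested. The test for pairing asked for a correlation above 0.1 in all 3 pairs. The replicate numbers failed it in the other 5 comparisons, where the lowest correlation of a pair was −0.07, −0.02, −0.57, 0.08 and 0.10 (Ikaros with Mezi, H3K27ac in Tex against Tact DMSO, H3K4me1 in both, H3K4me3 in Tex against Tact DMSO). The last failed narrowly, with 0.16, 0.10 and 0.12 against at most 0.06 between unlike numbers. With the replicate block it gave 586 loci, 268 higher and 318 lower, of which 498 were among the 742. Ikaros in Tex against Tact DMSO passed, although its lowest pair, 0.19, lay below its highest correlation between unlike numbers, 0.23. The cause was not tested except where given.

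The number of lists that passed with an estimated correlation was 0 for all 4 targets in Tex against Tact DMSO and 0 for H3K4me3 with Mezi. With the replicate block it was 2 for Ikaros in Tex against Tact DMSO and 4 for H3K4me3 with Mezi. Within 10 kb of the gene ends it was 1 for H3K27ac and 2 for H3K4me1 with Mezi. Estimating the correlation within 10 kb of the gene ends was also chosen after the data were seen, and each list that passed there without it had an adjusted p of 0.156 or more.

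Ikaros loci with Mezi numbered 2306 when centred, 0 when grouped by the treatment characteristic and 5480 without flanks; centring also turned KLF1 (0.11) and COL3A1 (0.48). With only the 6 libraries compared in the fit 1312 (H3K27ac), 93 (H3K4me1) and 250 (H3K4me3) loci passed in Tex against Tact DMSO, and 139 for H3K4me3 with Mezi. H3K4me1 loci with Mezi numbered 52 and 147 with pseudocounts of 50 and 1000 bp, 21 without scaling, 0 with the replicate block and 136 within 10 kb of the gene ends. H3K4me3 loci with Mezi numbered 18 and 51 with these pseudocounts, 47 without the filter, 59 without scaling, 18 with the replicate block, 18 within 10 kb of the gene ends and 60 without flanks. Within 10 kb of the gene ends CCND3 (H3K4me1 in Tex against Tact DMSO, 0.16) and ABL2 (H3K4me3 with Mezi, −0.02) turned.

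At a −log10 q of at least 5 the H3K4me1 peak number with Mezi differed by −191.7. With equally many peaks per library the Ikaros regions with Mezi numbered 468, of which 225 were only with Mezi and 243 only in Tex DMSO. This setting takes out a difference in peak number and cannot show a loss of peaks. Against regions in 1 to 5 libraries the occupancy odds ratio was 0.99 for gained and 1.35 for lost H3K27ac regions. With an overlap of at least 50% of the shorter peak, 74.2% and 71.9% of the peaks of Mezi replicates 2 and 3 lay in the same-numbered DMSO list.

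Leaving out each library in turn gave these lowest and highest numbers of loci: 5764 and 10000 for Ikaros with Mezi, 1208 and 2140 for H3K27ac, 206 and 1018 for H3K4me1 and 239 and 1499 for H3K4me3 in Tex against Tact DMSO, and 168 and 456, 0 and 34, and 7 and 15 for these marks with Mezi. Totals of regions were 5301 and 12055 for Ikaros, 9410 and 14297 for H3K4me1 and 1681 and 2268 for H3K4me3 in Tex against Tact DMSO, and 16686 and 29238, 7849 and 9558, and 900 and 1175 with Mezi. Leaving out a library loosens the rule for regions, so these totals could only rise. Differences in peak number were −7141.8 and 1784.7 for H3K4me1 in Tex against Tact DMSO, −1781.0 and 7145.5 for H3K4me1 with Mezi, and −395.7 and 1319.3 for H3K4me3 with Mezi. The covariance difference of the reversal was 0.04 and 0.32 for Ikaros, 0.022 and 0.081 for H3K27ac, −0.026 and 0.221 for H3K4me1, and 0.009 and 0.033 for H3K4me3. With replicate numbers kept together in the chance covariance it was −0.262 for Ikaros and −0.001 for H3K4me3, and from the Tex DMSO libraries alone −0.116 for Ikaros.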

Other observations

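The test of acetylation at the Ikaros peaks left with Mezi was set before its result was seen, and the regions between INHBA and GLI3 were singled out after their values were seen. On chromosome 7 the interval between INHBA and GLI3, which encodes a transcription factor of hedgehog signalling, held several of the widest changed regions. An H3K27ac region from 41867970 to 41876115 (8.1 kb) was in all 3 Tex DMSO lists and no Tact list. With Mezi, regions from 41808173 to 41813335 (5.2 kb), from 41828015 to 41834195 (6.2 kb) and from 41926324 to 41931712 (5.4 kb) were gained over Tex DMSO. Ikaros antibody regions from 41808646 to 41810274 and from 41832011 to 41833672, found in all 3 Mezi lists and no Tex DMSO list, lay within the first 2 of these. At the INHBA locus itself, H3K27ac covered 0 kb in Tact DMSO, 0.579 ± 0.167 kb in Tex DMSO and 5.52 ± 1.04 kb in Tex Mezi (SD, n = 3), with a log2 difference with Mezi of 2.81, SE 0.22 and an adjusted p of 0.000902 in limma.

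Whether the Ikaros peaks left with Mezi lay in acetylated chromatin more often than strong DMSO peaks was tested against equally many of the strongest peaks of the same-numbered Tex DMSO list. An H3K27ac peak of the same state and number overlapped 86.6%, 80.1% and 68.9% of the peaks of Mezi replicates 1, 2 and 3, against 81.1%, 66.0% and 61.4% of the strongest DMSO peaks and 55.2%, 54.0% and 55.3% of all DMSO peaks. The differences from the strongest peaks were 5.5, 14.1 and 7.5 points, all in the same direction, but short of the 10 points in all 3 pairs that had been set. The Mezi libraries also had more H3K27ac peaks, so this comparison leaves open whether the kept peaks differ.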
